A study of Mus musculus with 5 samples.

How the data were processed

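H3K23 propionylation (H3K23Pr), an acyl mark on lysine 23 of histone H3, was profiled by chromatin immunoprecipitation and sequencing in hearts of male C57BL/6J mice aged 12 weeks. The labels describe a diet without the branched-chain amino acids (BCAA: leucine, isoleucine and valine) and a control diet with them, each begun 4 days before a sham operation or transverse aortic constriction (TAC), a surgical narrowing of the aorta that loads the left ventricle with pressure. Hearts were collected 2 weeks after surgery, and each library came from a pool of 3 hearts. There were 4 H3K23Pr libraries, 1 for each combination of diet and surgery, and 1 pooled input library. The groups were taken from the sample titles, which match the design text. The treatment field of 3 samples differs from their titles, and the titles were followed.

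Per the labels' protocols the chromatin work was done by Active Motif. The aligner BWA, the peak caller MACS2 and the mouse genome build mm10 are named in the submitters' processing notes, without versions or roles. The deposited table lists 30965 merged regions, each an interval joined from the regions called in any of the 4 libraries. Per the file headers it holds an average and a peak signal (coverage) for every region and library, a flag for the libraries in which the region was called, a maximum tag number, counts of promoters and CpG islands, and the genes assigned to the region with their distance and position. No header states how the signal was scaled between libraries, so the values were taken as the authors deposited them. The authors also deposited log2 ratios of the average signal, which are plain ratios with no added constant. These equalled ratios recomputed from the signal columns to within 8.88e-16 and were used only for that check. The input library has no column in the table, so no input was subtracted and enrichment over input is not analysed here.

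The depth behind a region was derived from the deposited maximum tag number, which equals the largest average signal multiplied by the region's length and divided by 224. The same divisor turned each library's average signal into approximate tags. The tags summed over all regions, in units of 1e6, were 16.9 for the control diet sham library, 18.9 for the control diet TAC library, 17.0 for the BCAA-free sham library and 17.1 for the BCAA-free TAC library. Median tags per region were 245, 268, 248 and 239 in the same order. If the authors scaled the tags, the true numbers differ by that factor.

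The main value was the log2 ratio of average signal with a pseudocount of 1 added to both libraries, which understates the ratio of regions with low signal. Regions at least 1.5-fold higher or lower were counted, and medians over all regions were given with a 95% order-statistic interval. For named genes the fold is the plain ratio of average signals, with an exact 95% interval from the approximate tags (Clopper-Pearson). These intervals cover counting error only. For differences between diets the interval is a normal approximation on the log2 scale from the same tags. Each group had 1 library, so each comparison is between libraries and no p-value or SD was computed. The single comparisons and the difference between diets leave no residual degrees of freedom, and a test of diet or surgery in an additive model over all 4 libraries was not run. The difference of the TAC response between diets is the log2 ratio on the BCAA-free diet minus that on the control diet.

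Each of 18161 genes was represented by the region with the highest mean signal among the regions assigned to it. A region can serve several genes, and the 18161 genes rested on 11926 regions. Before the data were examined, 29 gene lists were fixed, of which 703 of 756 symbols had a region, 6 of them through an older symbol in the RefSeq table of GRCm38.p6. A list was called apart when its median lay at or below the 2.5th or at or above the 97.5th percentile of 10000 random lists of the same size matched on mean signal in 20 bins. By chance 1.45 of the 29 lists would be called apart in each comparison. The matching did not cover promoter or CpG-island class or region length, so a list can also lie apart through these, which was not tested. These percentiles describe these libraries and do not carry over to other hearts.

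The named genes followed a rule fixed at the same time. It takes the 8 highest and the 8 lowest regions of each comparison with mean signal at or above the median, a named gene and the same sign by peak signal. It adds 2 to 4 members with the largest ratios of each list described, and a fixed set of cardiac stress and BCAA genes (Nppa, Nppb, Myh7, Myh6, Acta1, Ankrd1, Atp2a2, Postn, Bcat2, Bckdha, Bckdhb, Pcca, Pccb and Ppm1k). The regions were restricted to those that represent a gene. Some genes that the rule names are not reported here. Coordinates are those of the deposited table.

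The alternatives were other pseudocounts (0.1 and 5), other fold thresholds (1.25 and 2), peak signal, centring on the median, removal of the trend on mean signal by lowess (fraction 0.3), and restriction to stronger, promoter, autosomal or called regions. For gene lists they were the mean of all regions of a gene, the region nearest to the gene start, peak signal, unmatched random lists and the detrended ratios. Counting each region once within a list was added after seeing the data. The scripts were tested on simulated tags for TAC against sham on the control diet over 30965 regions. All 100 regions raised 2-fold and all 100 raised 3-fold were recovered, and 0.237% of the 30765 unchanged regions were called higher. Of 200 random lists of 25 genes, 4.00% were called apart. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.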

Results

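H3K23Pr was compared across 4 heart libraries that crossed diet (BCAA-control or BCAA-free) with surgery (sham or TAC). Each library was a single pool of 3 hearts, so every difference below lies between pools and has no replicate check. Groups follow the sample titles, which the treatment field of 3 samples contradicts. Coordinates are on mm10. The table held 30965 regions covering 290.1 Mb, with a median length of 5599 bp, of which 9713 held a promoter and a CpG island and 16727 held neither. CpG-island promoters had the highest signal, with a median of 15.2 over the 4 libraries against 7.66 in regions with neither. The number of regions called was 23755 in the control diet sham library, 25729 in the control diet TAC library, 23579 in the BCAA-free sham library and 22787 in the BCAA-free TAC library. All 4 libraries shared 18068 regions, and 2249 were called in the control diet TAC library alone.

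The first comparison asked how H3K23Pr differed after pressure overload on the control diet. The natriuretic peptide gene Nppb, a classic marker of ventricular load, had 2.74-fold higher signal in TAC than in sham (95% counting interval 2.01 to 3.72). Its region, at chromosome 4, 147984200 to 147987999, is labelled as in the gene and holds 1 promoter. Skeletal actin Acta1, part of the fetal gene programme, was 1.98-fold higher (1.5 to 2.62), and Nppa, the atrial natriuretic peptide gene, was 1.66-fold higher (1.15 to 2.47). The Acta1 region is shared with Nup133, and the Nppa region lies downstream of Nppa and is shared with Clcn6. Signal at the region nearest to the Nppa start was 2.65-fold higher (2.03 to 3.55). Mean signal was 6.03 at the Nppb region, 4.67 at Acta1 and 6.52 at the downstream Nppa region, against a median of 9.36 over all regions. The fetal and stress list had a median log2 ratio of 0.29, within matched lists (percentile 77.3), with 4 of 22 genes at least 1.5-fold higher. Among matrix genes, Tnc, which encodes the injury-associated glycoprotein tenascin C, was 2.75-fold higher (1.94 to 4.02), and Thbs4 was 1.85-fold higher (1.46 to 2.38). The matrix list as a whole had a median of 0.24, within matched lists (percentile 41.1), with 4 of 42 genes at least 1.5-fold higher and 1 lower. The fibroblast gene Dcn (decorin) was 1.68-fold lower (1.54 to 1.84).

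Signal over the regions was higher in the control diet TAC library than in its sham library, with a median log2 ratio of 0.16 (0.151 to 0.159) over all regions and 0.26 over all genes. The gene lists of this comparison are therefore also given relative to all genes. At CpG-island promoters the median was 0.27, with 421 regions at least 1.5-fold higher and 3 lower, 96 and 9 after centring on the median over all regions, and 102 and 9 with the trend on mean signal removed. At regions with neither a promoter nor a CpG island it was 0.04. In total 1777 regions were higher and 677 lower, so 72.4% of these were higher. This share was 32.4% after centring and 59.7% with the trend removed. Counting noise alone gave at most 82 higher regions and 79 lower ones.

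**Figure D1:**
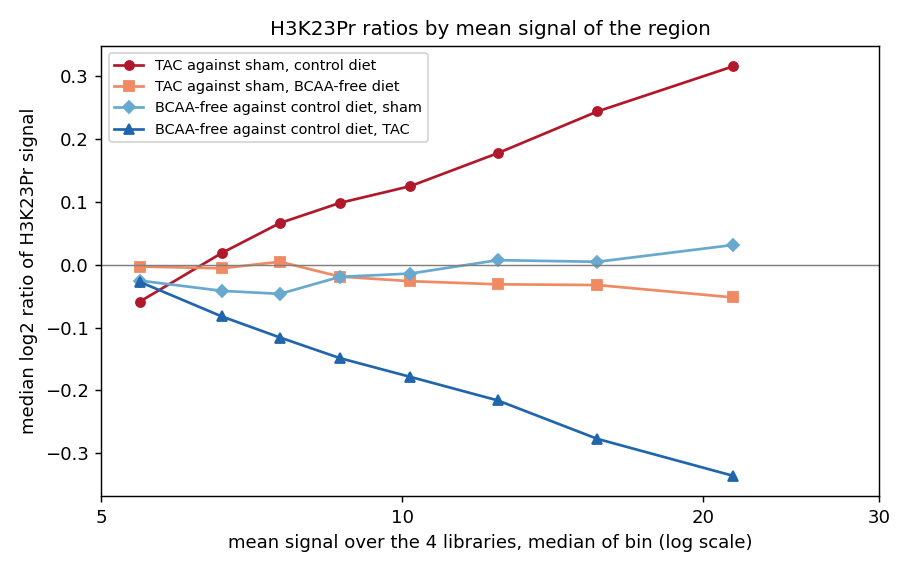
Median log2 ratio of H3K23Pr signal (vertical axis) in 8 bins of regions ordered by mean signal over the 4 libraries (horizontal axis, log scale), with 1 line for each comparison. In TAC against sham on the control diet the medians run from -0.06 in the weakest bin to 0.32 in the strongest, and in BCAA-free against control diet after TAC from -0.03 to -0.34.

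Against random lists matched on mean signal, 8 of the 29 lists lay low in TAC against sham on the control diet and 0 lay high. The lists were not matched on promoter or CpG-island class. Within bins of mean signal, CpG-island promoters lay 0.14 above regions with neither a promoter nor a CpG island. How far the low calls follow from region class was not tested. The fibroblast marker list lay 0.28 log2 below all genes, with a median ratio of -0.02 over 19 genes, 1 of them at least 1.5-fold lower and 0 higher. Its members Pi16 and Col1a1 were 1.38-fold (1.32 to 1.44) and 1.28-fold (1.21 to 1.35) higher. The smooth muscle and pericyte list had a median of 0.08, which is 0.18 below all genes, although Cnn1 (calponin) was 1.72-fold higher (1.11 to 2.68) and Myh11, smooth muscle myosin, 1.51-fold higher (1.16 to 1.96). The 25 genes of BCAA catabolism had a median of 0.16, which is 0.10 below all genes, with 1 gene at least 1.5-fold higher and 0 lower. That gene was Dld, the shared dehydrogenase subunit of the branched-chain and pyruvate complexes, at 1.54-fold (1.30 to 1.82). Bckdha was 1.21-fold higher (1.08 to 1.36) and Bcat2 1.16-fold higher (1.07 to 1.27), intervals that include the 1.196 of all genes. Bckdhb was 1.36-fold lower (1.19 to 1.55), but at the region nearest to the Bckdhb start the ratio was 0.96 (0.796 to 1.17), within counting error. The other low lists were hypertrophic signalling (0.11 below all genes), autophagy and proteolysis (0.09), mitochondrial dynamics and biogenesis (0.08), cardiac transcription factors (0.07) and fatty acid oxidation (0.04), all with medians above 0. Prkca was 1.46-fold higher (1.30 to 1.65) and Mtor 1.44-fold higher (1.23 to 1.69) within hypertrophic signalling. Each of the 8 calls was lost in at least 1 of 6 alternatives. With peak signal 6 were lost, the fibroblast list among them (percentile 7.19), BCAA catabolism was lost with the mean of all regions of a gene (percentile 18.6) and smooth muscle with the region nearest to the start (percentile 3.73). Mitochondrial dynamics held in 1 of the 6 alternatives, and fatty acid oxidation and cardiac transcription factors in 3.

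Among regions that represent a gene and have mean signal at or above the median, the highest ratios were those of Habp2 at 3.00-fold (2.17 to 4.15), Mgat3 at 2.55-fold (1.77 to 3.70), Edil3 at 2.49-fold (1.68 to 3.67) and Slc6a17 at 2.38-fold (1.71 to 3.38). The immediate early gene Nr4a2, an orphan nuclear receptor, was 2.06-fold higher (1.86 to 2.28) at chromosome 2, 57111400 to 57118799, within the gene. On the low side stood Lama2, a laminin chain of the muscle basement membrane, at 1.89-fold lower (1.59 to 2.26). Trdn (triadin), a protein of the calcium release complex, was 1.86-fold lower (1.57 to 2.22) at a region within the gene 171816 bp from its start. A region shared by Aspn and Omd, both small leucine-rich matrix proteoglycans, was 1.71-fold lower (1.5 to 1.97).

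The second comparison asked the same of mice on the BCAA-free diet. Regions of cardiomyocyte genes had higher signal in TAC than in sham: the 20 cardiomyocyte markers had a median log2 ratio of 0.54, all 20 were above 0, and 7 were at least 1.5-fold higher. Ryr2, the calcium release channel of the sarcoplasmic reticulum, was 1.90-fold higher (1.63 to 2.22), Ckmt2 (mitochondrial creatine kinase) 1.80-fold (1.61 to 2.01) and Corin, the protease that processes atrial natriuretic peptide, 1.74-fold (1.60 to 1.90). Fibroblast genes went the other way: the 19 fibroblast markers had a median of -0.47, with 8 at least 1.5-fold lower and 0 higher. Dcn was 2.13-fold lower (1.96 to 2.31), Tcf21, a fibroblast transcription factor, 1.98-fold lower (1.81 to 2.16) and the collagen gene Col1a2 1.82-fold lower (1.58 to 2.10).

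Endothelial markers also had higher signal in TAC than in sham on the BCAA-free diet, with a median of 0.43 over 20 genes. Their median signal was 14.35 in the BCAA-free sham library, the lowest of the libraries, and 19.3 in the BCAA-free TAC library. It was 18.0 and 24.0 in the control diet sham and TAC libraries. Kdr, the main receptor for vascular endothelial growth factor, was 1.73-fold higher (1.65 to 1.82), Sox17 1.67-fold (1.51 to 1.84) and Cldn5 (claudin 5) 1.59-fold (1.44 to 1.77). The sarcomere list had a median of 0.39, with 5 of 25 genes at least 1.5-fold higher, among them Myoz2 at 1.73-fold (1.57 to 1.90) and Ttn (titin) at 1.66-fold (1.44 to 1.92). Calcium handling and ion channel genes had a median of 0.39, with the calcium channel Cacna1c at 1.75-fold (1.66 to 1.85). The fetal and stress list had a median of 0.27. Nppa was 2.19-fold higher (1.56 to 3.16), Nppb 1.93-fold (1.41 to 2.64), Acta1 1.49-fold (1.11 to 2.01), and the region shared by Myh6 and Myh7 1.53-fold (1.43 to 1.64). The labelled distance of that shared region was -992 bp from the Myh6 start and 26950 bp from the Myh7 start. Signal at the region nearest to the Myh7 start was 1.70-fold higher (1.55 to 1.86).

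Energy metabolism lists lay above matched lists too. Fatty acid oxidation had a median of 0.17, with Ppargc1a, a coactivator of mitochondrial biogenesis, at 1.62-fold (1.51 to 1.74) and Fabp3, the heart fatty acid binding protein, at 1.5-fold (1.42 to 1.59). Oxidative phosphorylation had a median of 0.13 and 0 of 44 genes at least 1.5-fold higher. The medians were 0.11 for the TCA cycle, 0.08 for glycolysis and 0.06 for mitochondrial dynamics and biogenesis. On the low side, extracellular matrix and fibrosis had a median of -0.27, with 8 of 42 genes at least 1.5-fold lower and 1 higher. That gene was Thbs4, at 2.41-fold higher (1.91 to 3.06). Inflammation genes had a median of -0.21, and the region shared by Ccl2 and Ccl7, which encode monocyte chemokines, was 1.98-fold lower (1.70 to 2.31). Macrophage and immune markers had a median of -0.21, and the region of the complement genes C1qa, C1qb and C1qc was 1.47-fold lower (1.38 to 1.56). BCAA catabolism had a median of -0.02 and propionyl-CoA metabolism, the source of the propionyl group, of -0.01. Both lay within the range of matched lists. Housekeeping genes (-0.03), ribosomal proteins (0.02), core histones (-0.10), the histone acylation enzymes and readers (-0.06), smooth muscle markers (-0.03), immediate early genes (-0.11) and adipocyte markers (0.07) were also within it. So were erythroid and skeletal muscle markers (0.07), cardiac transcription factors (0.05), hypertrophic signalling (0.02), autophagy (-0.02), amino acid sensing (0.00053) and genes of other organs (-0.18). With peak signal calcium handling (percentile 97.2) and mitochondrial dynamics (percentile 74.9) were no longer apart. With the mean of all regions of a gene the macrophage (percentile 2.54) and inflammation (percentile 3.13) lists were not, nor was the macrophage list with each region counted once (percentile 4.26).

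**Figure D2:**
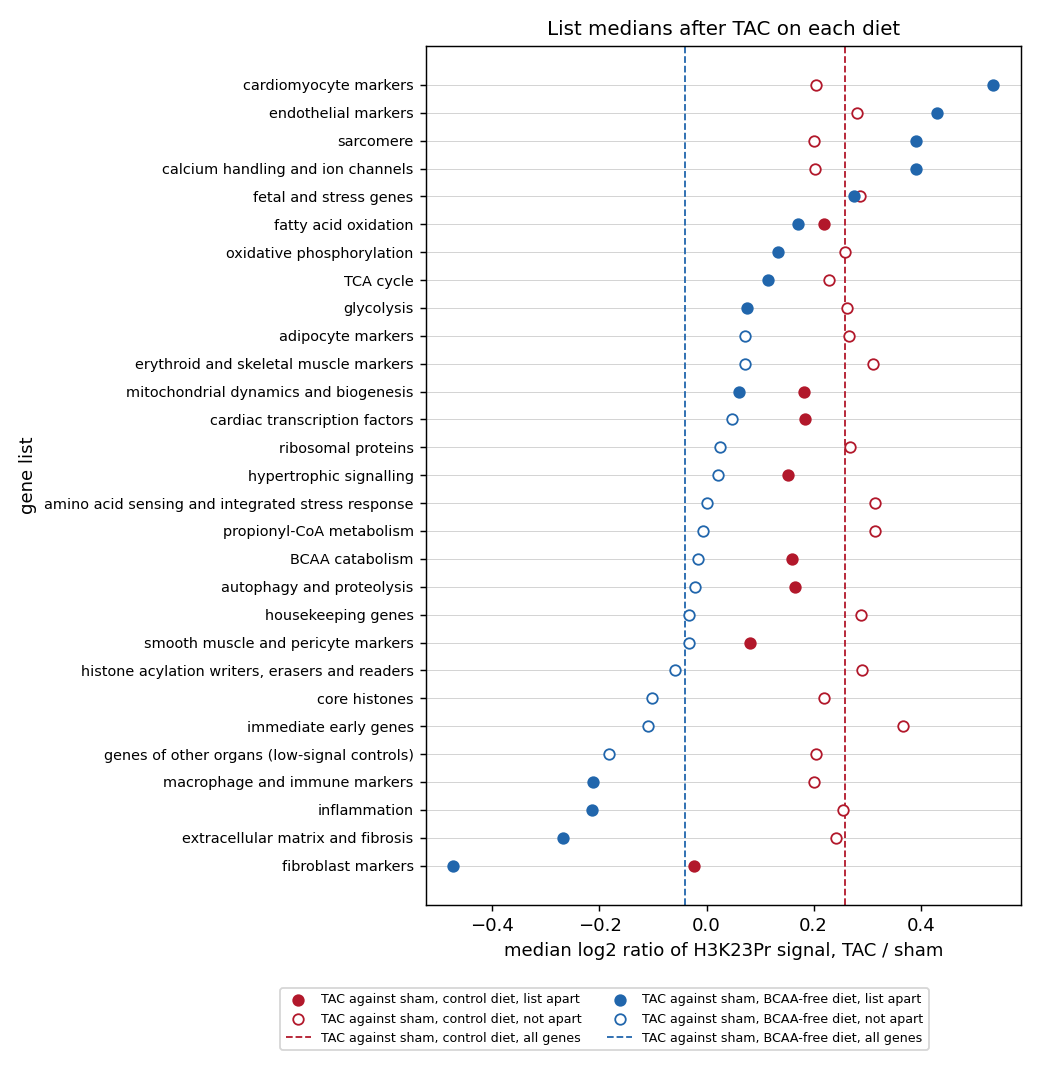
Median log2 ratio of H3K23Pr signal in TAC against sham (horizontal axis) for each of the 29 gene lists (vertical axis) on the control diet (red) and the BCAA-free diet (blue). Filled points are lists apart from matched random lists, open points are not, and dashed lines mark the medians of all genes at 0.26 and -0.04. The blue points spread from -0.47 for fibroblast markers to 0.54 for cardiomyocyte markers.

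Across all regions the median on the BCAA-free diet was -0.03 (-0.032 to -0.023), with 2492 regions at least 1.5-fold higher and 2858 lower. Counting noise gave at most 78 and 79. Among regions of at least median signal, higher ones included Adam1b at 3.93-fold higher (2.68 to 5.85), Ccdc147 at 2.76-fold higher (1.68 to 4.87), Stk32b at 2.20-fold higher (1.86 to 2.60) and Nfe2l3 at 2.03-fold higher (1.62 to 2.56). Lower regions included Ntrk2, a neurotrophin receptor, at 3.14-fold (2.19 to 4.53), Pyhin1 at 2.81-fold (1.97 to 4.04) and Penk (proenkephalin) at 2.64-fold (2.16 to 3.25). The Adam1b region, upstream of the gene, had a signal of 3.92 in the BCAA-free sham library against 12.7, 9.05 and 15.4 in the control diet sham, control diet TAC and BCAA-free TAC libraries.

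The responses to TAC on the 2 diets share no library. Across regions they had a Pearson r of 0.26 and a Spearman rho of 0.22, where counting noise gave an r of -0.002; neighbouring regions are not independent replicates. Of the 1777 regions at least 1.5-fold higher after TAC on the control diet, 328 were also higher on the BCAA-free diet, against 143 if the calls were independent, and 50 were lower, against 164. Of the 677 lower regions, 279 were also lower, against 62.5, and 66 were higher, against 54.5.

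The third comparison asked what the BCAA-free diet did without pressure overload. Fibroblast markers had higher signal on the BCAA-free diet, with a median of 0.36 and 17 of 19 genes above 0. Smoc2, a matricellular gene, was 1.83-fold higher (1.49 to 2.24), Ddr2, a collagen receptor, 1.49-fold (1.38 to 1.61) and Dpt (dermatopontin) 1.48-fold (1.34 to 1.64). Endothelial markers had lower signal, with a median of -0.35 and 19 of 20 genes below 0. Sox17 was 1.68-fold lower (1.52 to 1.86), Cldn5 1.60-fold (1.44 to 1.77) and Cdh5 (VE-cadherin) 1.46-fold (1.38 to 1.54).

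Extracellular matrix and fibrosis genes had a median of 0.24 in the same direction as the fibroblast markers, led by the collagen crosslinking enzymes Lox at 1.68-fold (1.48 to 1.91) and Loxl2 at 1.56-fold (1.34 to 1.83). Immediate early genes had a median of 0.16, with 22 of 24 above 0 and Nr4a2 at 1.61-fold (1.45 to 1.80). Inflammation genes had a median of 0.16, with Cxcl2 at 1.77-fold (1.38 to 2.27) and the Ccl2 and Ccl7 region at 1.66-fold (1.44 to 1.92). BCAA catabolism had a median of 0.14, with 0 of 25 genes at least 1.5-fold higher or lower. The branched-chain dehydrogenase component Dbt was 1.47-fold higher (1.19 to 1.81) and Bckdhb 1.26-fold (1.12 to 1.42). Pcca, a subunit of propionyl-CoA carboxylase, was 1.31-fold higher (1.05 to 1.62), Bcat2 1.18-fold (1.08 to 1.28) and Ppm1k, the phosphatase of the complex, 1.04-fold (0.93 to 1.16). By peak signal Bckdhb and Pcca had log2 ratios of the opposite sign (-0.11 and -0.09). Core histones had a median of 0.11. BCAA catabolism was not apart with peak signal (percentile 87.5), the mean of all regions of a gene (percentile 92.9) or the region nearest to the start (percentile 94.6). Core histones were not with peak signal (percentile 82.5) or with each region counted once (percentile 95.9). This comparison and that of TAC against sham on the BCAA-free diet share the BCAA-free sham library. Across regions their r was -0.57 and their covariance -0.0695, where counting noise gave -0.50 and -0.0106, and part of the opposite signs may come from the shared library.

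Between the sham libraries 855 regions were at least 1.5-fold higher and 812 lower, with a median of -0.01 over all regions. Nppb differed by 1.07-fold (0.738 to 1.54) and Acta1 by 1.00-fold (0.723 to 1.38), which is within counting error; by peak signal the log2 ratio of Nppb was -0.64. Large single differences were Sntg1 at 1.95-fold higher (1.69 to 2.26), Ms4a4d at 1.79-fold higher (1.52 to 2.09) and Alpl, tissue-nonspecific alkaline phosphatase, at 1.74-fold higher (1.61 to 1.89). A region near Ifi205 and the receptor genes Olfr432 and Olfr433 was 1.93-fold higher (1.77 to 2.09). Lower regions were Adam1b at 3.25-fold (2.19 to 4.86), Atp8a2 at 2.06-fold (1.68 to 2.56) and Csf2rb, a cytokine receptor subunit, at 1.92-fold (1.59 to 2.32).

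The fourth comparison set the diets side by side after TAC. Cardiomyocyte genes had higher signal on the BCAA-free diet: the 20 markers had a median of 0.28, which is 0.57 above all genes. Of these 18 were above 0 and 2 were at least 1.5-fold higher. Among the markers, Pln (phospholamban), the inhibitor of the calcium pump, was 1.85-fold higher (1.74 to 1.98) and Ryr2 1.79-fold (1.54 to 2.07). Actc1 (cardiac actin), on the sarcomere and fetal lists, was 1.84-fold higher (1.69 to 2.01). Myocd (myocardin), a cofactor of serum response factor on the cardiac transcription factor list, was 1.95-fold higher (1.87 to 2.04). Among the named regions Trdn had the largest ratio, 2.96-fold (2.53 to 3.48), and Mypn (myopalladin) was 2.17-fold higher (1.88 to 2.52). Macrophage and immune markers had a median of -0.43, which is 0.14 below all genes, with 16 of 25 genes below the all-gene median and 6 at least 1.5-fold lower. The C1qa, C1qb and C1qc region was 1.81-fold lower (1.70 to 1.92) and Cd74, the invariant chain of antigen presentation, 1.75-fold lower (1.51 to 2.03).

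Signal over the regions was lower in the BCAA-free TAC library than in the control diet TAC library. The median log2 ratio was -0.20 over all regions (-0.203 to -0.194) and -0.29 over all genes. The library that stood apart was control diet TAC, with a median signal of 10.2, against 9.24 in BCAA-free TAC. The control diet and BCAA-free sham libraries had 9.28 and 9.355. There were 1182 regions at least 1.5-fold higher and 2917 lower, so 28.8% of these were higher. The share was 74.2% after centring and 59.1% with the trend removed. At CpG-island promoters 11 regions were higher and 888 lower, with a median of -0.31; the counts were 47 and 183 after centring and 59 and 192 with the trend removed. Against random lists matched on mean signal, 14 lists lay high and 1 lay low. The lists were not matched on region class or length, and how far the calls follow from these was not tested. The median ratio was -0.07 in regions with neither a promoter nor a CpG island. It was -0.31 in the shortest length class and -0.05 in the longest. The sarcomere list lay 0.47 above all genes, calcium handling 0.43, cardiac transcription factors 0.26, fatty acid oxidation 0.24, fetal and stress genes 0.20, and the TCA cycle and autophagy lists 0.19 each. BCAA catabolism lay 0.18 above all genes, propionyl-CoA metabolism, glycolysis and hypertrophic signalling 0.17 each, oxidative phosphorylation 0.15 and mitochondrial dynamics 0.14. With peak signal cardiac transcription factors, hypertrophic signalling, autophagy, mitochondrial dynamics and the macrophage list (percentile 5.21) were not apart, and with the mean of all regions of a gene glycolysis was not.

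Within these lists the fatty acid transporter Cd36 was 1.74-fold higher on the BCAA-free diet (1.65 to 1.84) and Ppargc1a 1.59-fold higher (1.48 to 1.71). Bcat1, the cytosolic branched-chain aminotransferase, was 1.96-fold lower (1.42 to 2.71). Nppb and Acta1 had ratios of 0.75 (0.592 to 0.960) and 0.76 (0.590 to 0.967), intervals that include the 0.816 of all genes. Nppa had a ratio of 1.40 (1.04 to 1.90), the Myh6 and Myh7 region of 1.20 (1.13 to 1.28) and Ankrd1 of 1.04 (0.832 to 1.29). By peak signal the log2 ratio had the opposite sign for Nppb (0.13) and for the Myh6 and Myh7 region (-0.10). At the regions nearest to the gene starts the ratio was 0.85 (0.688 to 1.05) for Nppa, 1.45 (1.33 to 1.58) for Myh7 and 1.57 (1.35 to 1.83) for Ankrd1. Postn, a marker of activated fibroblasts, had a ratio of 0.81 (0.678 to 0.977), close to that of all genes. The ratio was 1.07 (0.989 to 1.17) for Bcat2, 0.92 (0.825 to 1.03) for Bckdha, 0.91 (0.809 to 1.02) for Pccb, 0.83 (0.670 to 1.03) for Pcca and 1.00 (0.890 to 1.12) for Ppm1k. For Bckdhb it was 1.04 (0.902 to 1.20) at its region of highest signal, 162218 bp from the start, and 2.52 (2.16 to 2.98) at the region nearest to the start. The lowest ratios were sought among regions that represent a gene, with mean signal at or above the median and the same sign by peak signal. They included Cdca7l at 3.28-fold lower (1.98 to 5.47), Habp2 at 3.15-fold lower (2.29 to 4.43) and Edil3 at 3.08-fold lower (2.05 to 4.80). Of the 1777 regions higher after TAC on the control diet, 44.9% were at least 1.5-fold lower in this comparison. Both comparisons use the control diet TAC library, and counting noise alone gave 14.5%. Of the 677 lower regions 18.9% were at least 1.5-fold higher here, where counting noise gave 27.2%. The noise draws held no shift between libraries, whereas the median ratio here was -0.20 over all regions. The noise shares also come only from regions that noise itself called. Neither share can therefore be read as more or less reversal than noise. Independent calls would give 167 lower regions in the first set, where 797 were seen, and 25.8 higher regions in the second, where 128 were seen. The r between them was -0.50 and the covariance -0.0598, against -0.50 and -0.0106 from counting noise.

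The last comparison asked whether the TAC response differed between the diets, as the log2 ratio on the BCAA-free diet minus that on the control diet. Contractile genes had a larger ratio on the BCAA-free diet: the cardiomyocyte list had a median difference of 0.28 and the sarcomere list of 0.20, which is 0.58 and 0.50 above all genes. Trdn differed by 1.5 (1.20 to 1.81), Pln by 0.85 (0.71 to 0.98), Cd36 by 0.90 (0.79 to 1.01), as log2 values without a pseudocount. Kdr differed by 0.69 (0.60 to 0.78) by average signal, and its sign was reversed by peak signal (-0.46). Matrix and immediate early genes had the opposite sign: Tnc differed by -1.25 (-1.96 to -0.53), Lox by -1.08 (-1.35 to -0.82), Nr4a2 by -1.05 (-1.25 to -0.85) and Egr3 by -0.97 (-1.15 to -0.78).

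The fibroblast list had a median difference of -0.51, the extracellular matrix list of -0.47 and the immediate early list of -0.48, which are 0.21, 0.17 and 0.18 below all genes, and these were the 3 lists below matched lists. Of the 19 fibroblast genes 16 lay below the all-gene median. With the trend on mean signal removed the immediate early list was not apart (percentile 8.08), and with peak signal the cardiac transcription factor, hypertrophic signalling, autophagy and glycolysis lists were not. Another 12 lists lay above. These were the cardiomyocyte, sarcomere, calcium handling, endothelial, cardiac transcription factor, autophagy, fatty acid oxidation, fetal and stress, TCA cycle, hypertrophic signalling, oxidative phosphorylation and glycolysis lists. Endothelial markers had a median of 0.04 (0.34 above all genes) and calcium handling of 0.14. Nppb differed by -0.50 (-1.12 to 0.11), Acta1 by -0.41 (-0.97 to 0.16), Nppa by 0.39 (-0.32 to 1.11) and Ankrd1 by -0.13 (-0.60 to 0.35), intervals that all include 0. By peak signal Nppb differed by 0.76, the opposite sign. The Myh6 and Myh7 region differed by 0.23 (0.09 to 0.38) and Atp2a2 by 0.09 (0.02 to 0.17), both with the opposite sign by peak signal (-0.07 and -0.44). At the regions nearest to the gene starts Ankrd1 differed by 0.68 (0.35 to 1.01), Myh7 by 0.45 (0.26 to 0.64) and Nppa by 0.16 (-0.42 to 0.74). The chemokine gene Cxcl2 differed by -1.61 (-2.11 to -1.12) and the region of Cxcl5, Pf4 and Ppbp by -1.59 (-1.99 to -1.19). Pkp2 (plakophilin), a desmosome protein of cardiomyocytes, differed by 0.98 (0.80 to 1.17), but by 0.09 with peak signal. Over all regions the median was -0.20, with 2105 regions at least 1.5-fold higher and 4572 at least 1.5-fold lower in the BCAA-free response. Counting noise gave at most 303 and 313. The higher regions were 31.5% of these, a share that was 67.5% after centring and 56.4% with the trend removed.

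**Figure D3:**
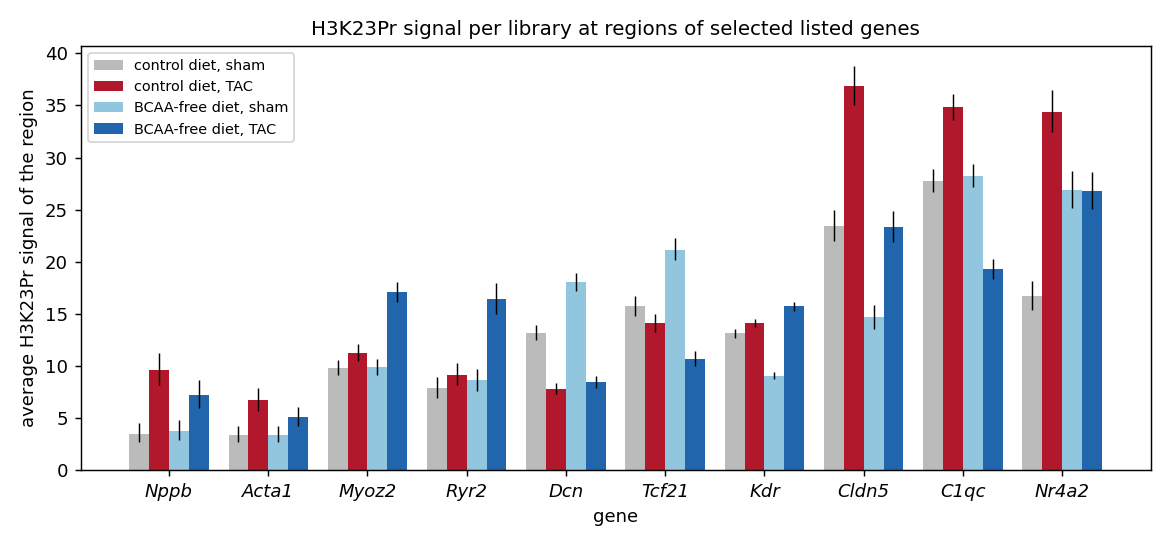
Average H3K23Pr signal (vertical axis) in each of the 4 libraries at the regions of 10 listed genes (horizontal axis), chosen after their values were seen. Bars are single libraries and the lines on them are exact 95% Poisson counting intervals. Dcn signal is 13.2 and 18.0 in the sham libraries and 7.83 and 8.47 in the TAC libraries, and Ryr2 signal is 16.4 in the BCAA-free TAC library against 7.86 to 9.18 in the others.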

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

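The tests on total tags, on the share of each cell type and on regions with high peaks were chosen only after the results they bear on had been seen. The differences listed first were not tested, since each group had 1 library.

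Several gene groups had TAC ratios of opposite sign on the 2 diets, each at least 0.1 from 0. The extracellular matrix list had medians of 0.24 on the control diet and -0.27 on the BCAA-free diet, a difference of -0.51. Inflammation genes had medians of 0.25 and -0.21 (difference -0.47), immediate early genes 0.37 and -0.11 (-0.48), and macrophage and immune markers 0.20 and -0.21 (-0.41). Core histones had 0.22 and -0.10 (-0.32), and genes of other organs, listed as low-signal controls although their median signal was 14.7, 0.20 and -0.18 (-0.39). Pcca, a propionyl-CoA carboxylase subunit, had log2 ratios of 0.32 and -0.28 (-0.60). Without a pseudocount its difference was -0.66 (-1.08 to -0.23), an interval that includes the median difference over all genes. By peak signal its ratio on the control diet was 0.03. The median difference over all genes was -0.30. By the median of per-gene differences the macrophage (-0.33), core histone (-0.34), other organ (-0.34) and inflammation (-0.41) lists lay within the range of matched lists, so their opposite signs are not set apart from the shift of all genes.

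CpG-island promoters had higher H3K23Pr after TAC on the control diet, and that library had the highest median signal, 10.2. A uniform difference in signal over background should act alike on regions of the same strength, but within 20 bins of mean signal these promoters still lay 0.14 (0.131 to 0.156) above regions with neither a promoter nor a CpG island. Within 20 bins of mean peak signal the gap was 0.16 (0.152 to 0.178). Both intervals come from resampling regions as if they were independent, so they do not cover differences between libraries or hearts. More tags in total would shift every region, yet the median of regions with neither was 0.0371 (0.0299 to 0.0439). Over all regions simulated counting noise gave at most 82 higher regions, against 1777 observed. No such count was made for CpG-island promoters alone. A library-specific enrichment of CpG-rich or open chromatin that does not follow signal strength was not tested, and it stays open with pressure overload itself, since TAC and library cannot be separated with 1 pool per group.

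Cardiomyocyte and fibroblast genes lay far apart between the BCAA-free TAC and sham pools, and a trend of the ratio with mean signal does not account for it, since their medians still differed by 1.02 with that trend removed. A lower share of cardiomyocytes in the sham pool as the only change would move the other cell types together, but the endothelial and fibroblast medians differed by 0.90 with opposite signs. This cannot exclude such a lower share joined with a change in another cell type. Between the sham pools the cardiomyocyte median was 0.02, within matched lists. Median signal of that list was 18.0 in the BCAA-free TAC library, against 11.8 and 14.8 in control diet sham and TAC and 12.3 in BCAA-free sham. A higher cardiomyocyte share in the BCAA-free TAC pool was not tested. A higher share of fibroblast chromatin in the BCAA-free sham pool may contribute to the fibroblast side: 36 matrix genes outside the fibroblast list had a median of -0.24, at the 0.01 percentile of matched lists. These genes are most of the 42 on the matrix list, already seen to lie low here. This result was therefore nearly fixed in advance and adds little. Dcn, a fibroblast gene of high expression, had a signal of 18.0 in that pool against 13.2 in the control diet sham pool, and 6 of the 19 fibroblast and 16 of the 20 cardiomyocyte markers are also on another list. A difference of diet and surgery in the marks of each cell type stays open too and was not tested.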

How the results depend on the processing

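Counting each region once was chosen after the data were seen. The input-subtracted alternatives and H3K23Pr against input were not run. No paired analysis was run and no library was left out, since each group has 1 library. Of the list calls that were apart, 315 held and 39 were lost over the alternatives, 19 of those with peak signal. For named genes and regions 1582 values stayed within counting error, 503 moved and 6 reversed, and the cause was not tested. Reversed means a change of sign where the main ratio was at least 1.5-fold, so sign changes of smaller ratios are not among the 6. The highest and lowest regions of each comparison were chosen to have the same sign by peak signal, so they could not reverse with it. Reversed were Bckdhb in TAC on the BCAA-free diet with the region nearest to the start (0.62), Cacna1c in diet after TAC (-0.52), and, in the difference between diets, Xirp2 (-0.087), Pfkfb1 (-0.30), Myocd (-0.0042) and Kdr (-0.46), all with peak signal except Bckdhb. In TAC on the control diet 4 lists were apart with peak signal and 5 with unmatched lists, against 8. Over regions with mean signal at or above the median the regions called were 14565 and 15233 in the control diet sham and TAC libraries and 14613 and 14313 in the BCAA-free sham and TAC libraries. The median for diet in sham changed sign in 3 restrictions below. Only region counts more than 1.5 times from the main count, and medians outside their interval, are given below for each setting, except the higher counts with peak signal. With a pseudocount of 0.1 the region counts were 1222 lower for diet in sham. The medians were 0.17 for TAC on the control diet, -0.22 for diet after TAC and -0.22 for the difference between diets. With a pseudocount of 5 the region counts were 477 higher and 72 lower for TAC on the control diet, 552 higher and 906 lower for TAC on the BCAA-free diet and 141 higher and 100 lower for diet in sham. They were 285 higher and 804 lower for diet after TAC and 694 higher and 1761 lower for the difference between diets. The medians were 0.12 for TAC on the control diet, -0.021 for TAC on the BCAA-free diet, -0.14 for diet after TAC and -0.15 for the difference between diets. Over regions with mean signal at or above the median the region counts were 629 higher and 43 lower for TAC on the control diet, 643 higher and 729 lower for TAC on the BCAA-free diet and 160 higher and 127 lower for diet in sham. They were 182 higher and 1304 lower for diet after TAC and 355 higher and 2255 lower for the difference between diets. The medians were 0.23 for TAC on the control diet, -0.037 for TAC on the BCAA-free diet, 0.010 for diet in sham, -0.26 for diet after TAC and -0.28 for the difference between diets. After centring the region counts were 741 higher and 1544 lower for TAC on the control diet, 2605 higher and 906 lower for diet after TAC and 3911 higher and 1880 lower for the difference between diets. With the trend removed the region counts were 1928 higher and 1336 lower for diet after TAC and 2409 lower for the difference between diets. With peak signal the region counts were 5171 higher and 1049 lower for TAC on the control diet, 2754 higher and 4768 lower for TAC on the BCAA-free diet and 1830 higher and 1938 lower for diet in sham. They were 1117 higher and 9677 lower for diet after TAC and 2113 higher and 11311 lower for the difference between diets. The medians were 0.28 for TAC on the control diet, -0.13 for TAC on the BCAA-free diet, 0 for diet in sham, -0.40 for diet after TAC and -0.41 for the difference between diets. Over promoter regions the region counts were 614 higher and 62 lower for TAC on the control diet, 368 higher and 560 lower for TAC on the BCAA-free diet and 114 higher and 109 lower for diet in sham. They were 113 higher and 1298 lower for diet after TAC and 208 higher and 2040 lower for the difference between diets. The medians were 0.24 for TAC on the control diet, -0.049 for TAC on the BCAA-free diet, 0.0029 for diet in sham, -0.29 for diet after TAC and -0.29 for the difference between diets. Over regions called in the compared libraries the region counts were 527 higher and 81 lower for TAC on the control diet, 865 higher and 843 lower for TAC on the BCAA-free diet and 225 higher and 96 lower for diet in sham. They were 326 higher and 1067 lower for diet after TAC and 565 higher and 2018 lower for the difference between diets. The medians were 0.16 for TAC on the control diet, -0.023 for TAC on the BCAA-free diet, 0.0075 for diet in sham, -0.19 for diet after TAC and -0.22 for the difference between diets. At the lower fold threshold the region counts were 8258 higher and 2628 lower for TAC on the control diet, 6271 higher and 6617 lower for TAC on the BCAA-free diet and 3575 higher and 3652 lower for diet in sham. They were 3311 higher and 10623 lower for diet after TAC and 4666 higher and 11731 lower for the difference between diets. At the upper fold threshold the region counts were 199 higher and 46 lower for TAC on the control diet, 210 higher and 426 lower for TAC on the BCAA-free diet and 47 higher and 71 lower for diet in sham. They were 148 higher and 281 lower for diet after TAC and 443 higher and 666 lower for the difference between diets.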

Other observations

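The gene families here were chosen after the data were seen, from 18 defined by symbol. Chemokine genes (Ccl and Cxcl, 29 genes) had a median log2 ratio of 0.16 in BCAA-free against control diet sham hearts, with 7 at least 1.5-fold higher and 0 lower. In TAC against sham on the BCAA-free diet their median was -0.41 (-0.37 relative to all genes), with 11 lower and 0 higher. The median difference of the TAC response between diets was -0.70 (-0.40 relative to all genes), with 15 of 29 genes at least 1.5-fold lower. All of these chemokine comparisons use the BCAA-free sham library, so they are not independent of each other. BCAA-free against control diet after TAC does not use that library. There the chemokine median was -0.41 (-0.12 relative to all genes, percentile 0.48 of matched lists), with 11 genes lower and 0 higher. In TAC against sham on the control diet the chemokines lay within matched lists (percentile 70.4). Interferon-activated genes (Ifi) lay below matched lists after TAC on both diets, with medians of 0.05 on the control diet and -0.29 on the BCAA-free diet, which are -0.21 and -0.25 relative to all genes. The tRNA synthetase genes, which charge tRNAs with amino acids, had a median of 0.36 after TAC on the control diet, at percentile 99.2 of matched lists. Zinc finger genes (Zfp, 317 genes) had a median of -0.36 in BCAA-free against control diet hearts after TAC, -0.06 relative to all genes. Hox genes had a median of 0.10 in the sham diet comparison, but the 36 genes rest on 13 regions.

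The longest region was 269599 bp at Ablim1, an actin-binding protein gene, on chromosome 19, with signal 18.7, 21.2, 17.1 and 24.1 in the control diet sham, control diet TAC, BCAA-free sham and BCAA-free TAC libraries. A region of 197599 bp covered Zbtb16 with signal between 34.6 and 38.2. Among the strongest regions was a region of 41399 bp labelled downstream of Txnip, a regulator of glucose uptake, with signal from 63.3 to 68.2. Another, of 36799 bp and labelled upstream of Fkbp5, a glucocorticoid target, had signal from 57.5 to 67.1. These labels do not say whether a region also covers the gene. The 308 longest regions, from 62399 bp, had medians of 0.10 after TAC on the control diet and 0.10 on the BCAA-free diet. The 7811 shortest had 0.22 and -0.05.

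Neighbouring regions had similar ratios. The correlation between a region and the next on its chromosome was 0.31 for TAC against sham on the control diet and 0.40 on the BCAA-free diet. It was 0.06 and 0.02 between regions 20 places apart, across regions that are not independent replicates.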
